A study of Mus musculus with 2 samples.

How the data were processed

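The series holds 2 droplet single-cell libraries made with 10x Genomics chemistry, 1 of CD45+ cells from DGAT1 knockout B16-F10 tumours and 1 from WT tumours. Per the labels, 3 tumours stand behind each group, the tissue was digested with collagenase and DNase, and living CD45+ single cells were sorted. The authors deposited counts: whole-number UMI counts per gene and barcode, not normalized, for 32285 genes and all barcodes. Per the file headers, the matrices were written by Cell Ranger 7.2.0, and per the submitters' processing notes the genome build was mm10. The annotation behind the counts and any filters are not given in the sources used here. Gene positions were taken from the GENCODE M21 annotation of that build.

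Cells were called in each library on its own. Barcodes above a UMI threshold, the 99th percentile of the leading barcodes divided by 10, were taken as cells; it came to 9254 UMIs in the knockout library and 16616 in the WT library. Barcodes below it with at least 500 UMIs were kept when their profile differed from free RNA in a Monte Carlo test with 10000 simulations at a false discovery rate of 0.01. This gave 12903 and 10800 cells. Cells with fewer than 250 genes or more than 10% mitochondrial UMIs were left out, leaving 11451 and 9344. Scrublet in scanpy 1.11.5, run per library, marked 411 doublets (3.59%) and 191 (2.04%), under the 9.16% and 7.48% given by 0.8% per 1000 cells, and these were removed. On simulated barcodes the calling kept 100% of large cells, 94.5% of small cells in the knockout library and 98.5% in the WT library, and 0.25% of free RNA barcodes. The small cells were thinned copies of the largest barcodes, and the free RNA barcodes were drawn from the profile used in the test. These values check the computation only, because cell types of low RNA content were not simulated.

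Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes and 30 principal components were computed with numpy over both libraries together without integration. A graph of shared neighbours among 15 neighbours per cell (scikit-learn 1.9.0) was clustered by the Leiden method (leidenalg 0.10.2) at resolution 1. T, NK and innate lymphoid cells and mononuclear phagocytes were clustered again by the same steps. Clusters were named by hand from fixed markers as a type-like class, and clusters whose leading genes went against a name stayed numbered or unnamed. Names were given after the clusters were seen. The markers, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. Shares are of CD45+ types, 10956 cells in the knockout library and 8851 in the WT library, leaving out melanoma-like and fibroblast-like cells.

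With 1 library per group there is no replicate check, so no test, p-value or count of changed genes was computed. UMIs were summed per class and library and divided by the class total into CPM, with exact Poisson intervals for levels, exact binomial intervals for shares and exact conditional intervals for ratios. They cover counting error only, at 95%. Classes with at least 100 cells in each library were compared, which gave 12. The median log2 ratio of each of 26 fixed lists was taken over members with at least 50 UMIs in the class and set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. The 12 medians that lead the text were chosen from 301 after they were seen. Named genes had at least 50 UMIs in a library and a ratio of at least 1.5 either way, without mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor segment genes, Gm and Rik models, Xist and Y-linked genes, and without genes for which free RNA gave 25% or more of the UMIs in the higher library. They were ranked by the interval bound nearest to 0, with 10 each way in the 3 largest classes and 3 each way in the others, 114 in all, of which the text prints a part chosen after their values were seen. Members of the fixed lists are given beside them.

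Free RNA, read from barcodes of at most 100 UMIs, made up an estimated 2.22% of UMIs in knockout cells and 2.38% in WT cells, from macrophage and melanoma genes in lymphocytes. From melanoma genes alone the estimates were 4.00% and 4.30%. On simulated counts, ratio intervals held the true ratio for 95.4% of unchanged genes in CD8 T-like cells, and excluded 1 for 91% of genes changed by 1.5-fold and 99% of genes changed by 2-fold in those cells. Of unchanged simulated lists there, 7% fell outside the central 95% of random lists. The simulated counts were independent Poisson draws, the model that the intervals assume. They check the computation only, because UMIs that lie in few cells and list genes that vary together were not simulated.

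Results were recomputed under 10 alternatives: only barcodes above the UMI threshold, at least 1000 UMIs, at most 5% mitochondrial UMIs, doublets kept, a clustering resolution of 2, cells thinned to matched depth, marker gates in place of clusters, median-of-ratios scaling, free RNA subtracted, and list members of at least 200 UMIs. The numeric minimums of the gates were set after the data were seen but before the gated values. Another 3 alternatives, unnamed cells left out of the denominator, each cluster of a class weighted alike, and WT barcodes thinned to matched depth before cells were called again (8770 cells) and gated, were chosen after seeing the data. Clusters made under an alternative took the class that most of their cells had before. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.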

Results

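Immune cells of subcutaneous B16-F10 tumours, a transplantable mouse melanoma, were profiled by droplet single-cell RNA sequencing. The tumours came either from melanoma cells lacking DGAT1, an enzyme that makes triglyceride from diacylglycerol, or from WT melanoma cells. Per the labels, tumours were taken on day 14, 3 per group, and living CD45+ cells were sorted. Each group has 1 library, with no map from cells to tumours, so no test between the groups was possible and each value below describes these 2 libraries. The knockout library held 202946827 UMIs and the WT library 235652476. After filtering, 11040 and 9153 cells remained, with medians of 10673 and 13934 UMIs and of 3249 and 3734 genes per cell. Expression is given as CPM, the UMIs of a gene scaled to a common total per class and library. Where 2 values stand side by side, the knockout library comes first. Intervals are exact 95% intervals that cover counting error only and leave out that the UMIs of a gene can lie in few cells, and log2 ratios are knockout over WT.

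Dgat1 (ENSMUSG00000022555), a protein-coding gene on the minus strand of chromosome 15 from 76502015 to 76511953 (mm10), was read first. Its level over all kept cells was 43.9 CPM in the knockout library (42.9 to 44.9) and 37.3 CPM in the WT library (36.4 to 38.2). In CD8 T-like cells it was 68.8 and 79.2 CPM. The edit is in the implanted tumour cells and the sort took host cells, so these levels do not check the labels. In the few melanoma-like cells that passed the sort, Dgat1 was at 18.3 CPM in the knockout library (15.2 to 21.7) and 28.4 CPM in the WT library (26.5 to 30.5). A 3' tag outside the edited part would be counted from an edited gene too, and the edited part is not given in the sources used here, so this level checks nothing either.

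The design asks how the immune cells of a tumour differ when its tumour cells lack DGAT1, and the first comparison is of cell types. Macrophage-like cells, the tissue phagocytes marked by complement C1q genes, made up 10.8% of CD45+ types in the knockout library (10.2 to 11.3) and 28.5% in the WT library (27.6 to 29.5), a ratio of 0.377 (0.352 to 0.404). Monocyte-like cells, marked by Ly6c2 and Ccr2 and able to enter tissue from blood, made up 18.7% (17.98 to 19.5) and 8.11% (7.55 to 8.70), a ratio of 2.31 (2.12 to 2.51). There were 1.74 monocyte-like cells per macrophage-like cell in the knockout library and 0.285 in the WT library. The mononuclear phagocytes as a whole took nearly equal shares, 59.3% and 59.8%. Phagocyte cluster 2 held more of the macrophage-like cells of the knockout library than any other cluster, and phagocyte clusters 4 and 3 held more of those of the WT library.

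CD8 T-like cells, the main cytotoxic T cells, were 23.1% of CD45+ types in the knockout library (22.3 to 23.9) and 20.8% in the WT library (19.97 to 21.7). Among T, NK and innate lymphoid cells alone the direction turned, with 66.3% and 71.4% and a ratio of 0.928 (0.873 to 0.986), and over CD45+ types the interval of the ratio spanned 1 with marker gates (0.972 to 1.10) and above the UMI threshold (0.959 to 1.11). NK-like cells, innate killers, were 5.09% and 2.90%, a ratio of 1.75 (1.51 to 2.04). Treg-like cells, which restrain other T cells, were 1.56% and 1.30%, and the interval of their ratio spanned 1 (0.943 to 1.54). The number of CD8 T-like cells per Treg-like cell was 14.8 in the knockout library (12.7 to 17.4) and 16.02 in the WT library (13.3 to 19.5), a difference within counting error. CD8 T-like cells per macrophage-like cell numbered 2.15 and 0.730. CD4 T-like cells were few, 129 and 21 cells, and the ratio of their shares was 4.96 (3.11 to 8.29).

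Among the remaining types, neutrophil-like cells were 2.95% and 1.57%, non-classical monocyte-like cells 5.22% and 3.07%, and cDC2-like cells, dendritic cells that mainly present antigen to CD4 T cells, 6.22% and 3.71%. Plasmacytoid dendritic-like cells numbered 127 and 37, a share ratio of 2.77 (1.91 to 4.12). Mature dendritic-like cells, which carry antigen to lymph nodes, had a share ratio of 1.36 (1.12 to 1.66). The cDC1-like cells, which cross-present antigen to CD8 T cells, went the other way, with 1.16% and 1.68% and a ratio of 0.689 (0.539 to 0.878), or 0.761 (0.570 to 1.02) with at most 5% mitochondrial UMIs, as did B-like cells with 66 and 149 cells and a ratio of 0.358 (0.264 to 0.481). Ratio intervals spanned 1 for gamma-delta T-like cells (0.888 to 1.92), for lymphoid cluster 6 (0.925 to 1.38) and for phagocyte cluster 0 (0.970 to 1.15), although above the UMI threshold the ratios of the last pair were 5.41 (2.60 to 12.99) and 1.66 (1.45 to 1.91). Cells left unnamed were 2.28% and 7.78%, beside unnamed lymphoid cells at 1.03% and 1.40% and unnamed phagocytes at 2.05% and 1.57%. The UMI threshold above which a barcode was taken as a cell without a further test was 9254 in the knockout library and 16616 in the WT library, and the WT cells were deeper, both of which can set shares of cell types that differ in RNA content. Marker gates in place of clusters brought the log2 ratio of cDC2-like cells from 0.75 to 0.10, with an interval that spanned 0, that of monocyte-like cells from 1.21 to 0.65 and that of CD4 T-like cells from 2.31 to 1.40. With only barcodes above the UMI threshold, the log2 ratio of CD4 T-like cells was 5.62, of non-classical monocyte-like cells 3.37, of plasmacytoid dendritic-like cells 2.80 and of NK-like cells 1.51, against 2.31, 0.76, 1.47 and 0.81 with all called cells.

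**Figure D1:**
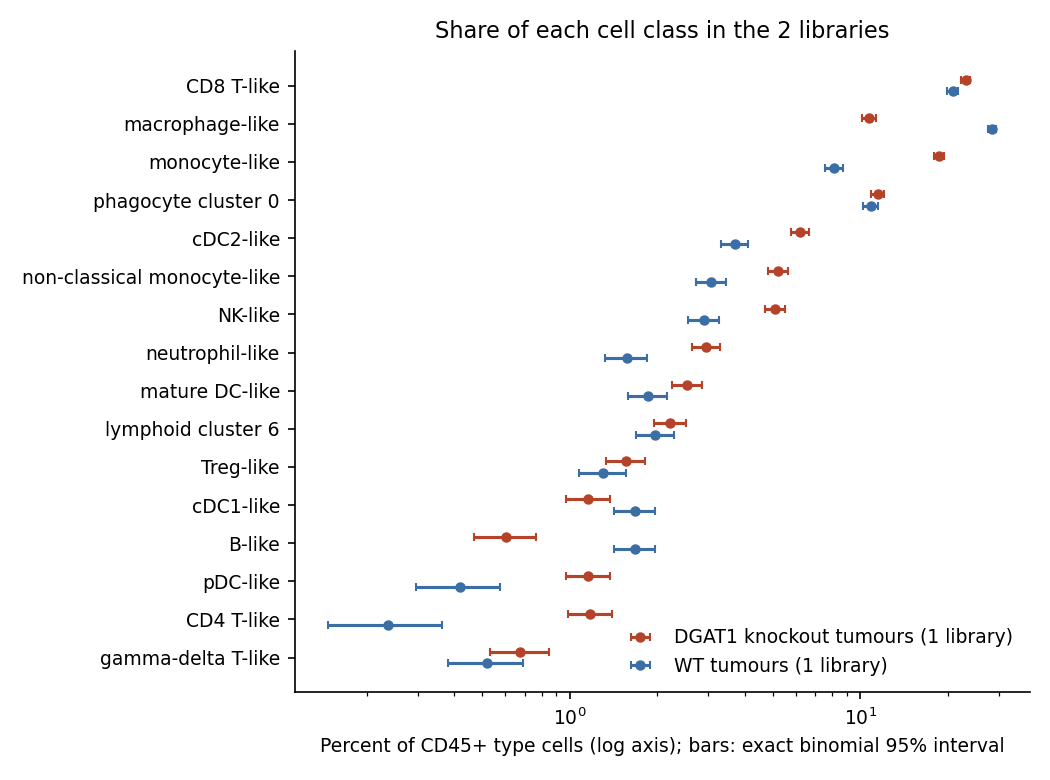
Share of each cell class among CD45+ type cells, in percent on a log axis, in the DGAT1 knockout library and the WT library (1 library each); bars are exact binomial 95% intervals, which cover counting error only. Macrophage-like cells sit at 10.8% and 28.5%, and monocyte-like cells at 18.7% and 8.11%.

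In CD8 T-like cells, part of the cytotoxic effector list was lower in the knockout library. Prf1 (chromosome 10, 61297833 to 61304680), which encodes the pore former perforin, was at 350 CPM against 969 CPM in the WT library, a ratio of 0.362 (0.356 to 0.368). Gzmb (chromosome 14, 56258838 to 56262260), which encodes the protease granzyme B, was at 921 and 1758 CPM, and the T cell chemokine gene Ccl3 at 391 and 814 CPM. Ifng, the gene of interferon gamma, was at 186 and 292 CPM. Of the 18 measured cytotoxic effectors, 8 were at least 1.5-fold lower and 3 at least 1.5-fold higher. The higher members were Gzma (49.0 and 20.5 CPM), the dendritic cell attractant Xcl1 (360 and 192 CPM) and the death ligand gene Tnfsf10 (89.0 and 58.8 CPM).

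The median log2 ratio of the cytotoxic effectors was -0.44, at percentile 0 among 10000 random lists matched on expression, which is a description of these libraries. The list median was below 0 in 12 of 12 classes, from -0.55 to -0.0062, so a value below 0 alone does not set CD8 T-like cells apart. This count of signs does not show that the classes shared a change. In NK-like cells the median was 0.061 above the UMI threshold. In neutrophil-like cells the 91 WT UMIs of Gzma came from 4 cells. The CD8 T-like cells of the knockout library were most numerous in T cell cluster 1 and those of the WT library in T cell cluster 2, whose leading genes include Prf1, Gzmb and Gzmc to Gzmf themselves. With each cluster weighted alike in both libraries the median was -0.021, and 2 of the 8 lower members, Prf1 at -0.95 and Ccl3 at -0.66, remained at least 1.5-fold lower. Gzmb stood at -0.48 and Ifng at -0.27 under that weighting, while Gzmc, Gzmd, Gzme and Gzmf, at -0.69, -1.74, -1.38 and -0.82 in the class as a whole, stood at 0.20, -0.16, 0.18 and 0.54. Within clusters, Prf1 and Gzmb were lower in 11 of 12. These members were singled out after their values were seen.

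The naive and memory T cell list had a median of 0.45 in CD8 T-like cells, with 5 of 14 measured members at least 1.5-fold higher and 0 as much lower. The chemokine receptor gene Cxcr3 was at 20.97 and 8.19 CPM, Slamf6 at 17.5 and 9.64 CPM and Tcf7, which encodes a transcription factor of memory-like T cells, at 9.20 and 4.85 CPM. With each cluster weighted alike the median was 0.11, and 1 of these 5 members remained at least 1.5-fold higher. Klf2 went the other way, from -0.34 in the class to -0.83 under that weighting. Within clusters, Klf2 and Cd27 were each lower in 11 of 12. Among inhibitory receptors and exhaustion genes the median was -0.072, with 0 of 15 at least 1.5-fold higher and 3 as much lower. Pdcd1, which encodes PD-1, was at 360 and 350 CPM, and Tox at 1345 and 1192 CPM, whereas Ctla4 was at 136 and 288 CPM and Tnfrsf9 at 282 and 525 CPM.

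Hypoxia and glycolysis genes in CD8 T-like cells had a median of -0.57, with 10 of 22 at least 1.5-fold lower and 0 as much higher. The median was below 0 in 12 of 12 clusters, and 5 of the 10 remained at least 1.5-fold lower under equal weights per cluster, with a median of -0.42. Across classes, the list median was below 0 in 10 of 12, down to -0.60. Bnip3, a hypoxia-responsive mitophagy gene, was at 19.4 and 46.8 CPM, the lactate exporter gene Slc16a3 at 38.1 and 78.7 CPM, and Pgk1 at 460 and 689 CPM. The dissociation stress list was at -0.46 in these cells and above 0 in 6 of 12 classes, with Jun at 14.0 and 51.1 CPM and Hspa1a at 127 and 210 CPM in CD8 T-like cells. The melanoma list, made of genes of tumour cells, was at -1.80, with Pmel at 4.31 and 17.4 CPM, of which free RNA gave an estimated 60.2% and 66.4%. The lipid-associated macrophage list was at -0.73, with free RNA giving an estimated median of 27.8% and 26.4% of the UMIs of its members, and lipid storage and oxidation at -0.17, lipid synthesis and cholesterol at 0.070, ferroptosis and iron at -0.012, cell cycle at 0.082 and costimulation at -0.10. The median over all genes with at least 50 UMIs in these cells was 0.067, so the lipid synthesis and cell cycle lists stood near that level.

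**Figure D2:**
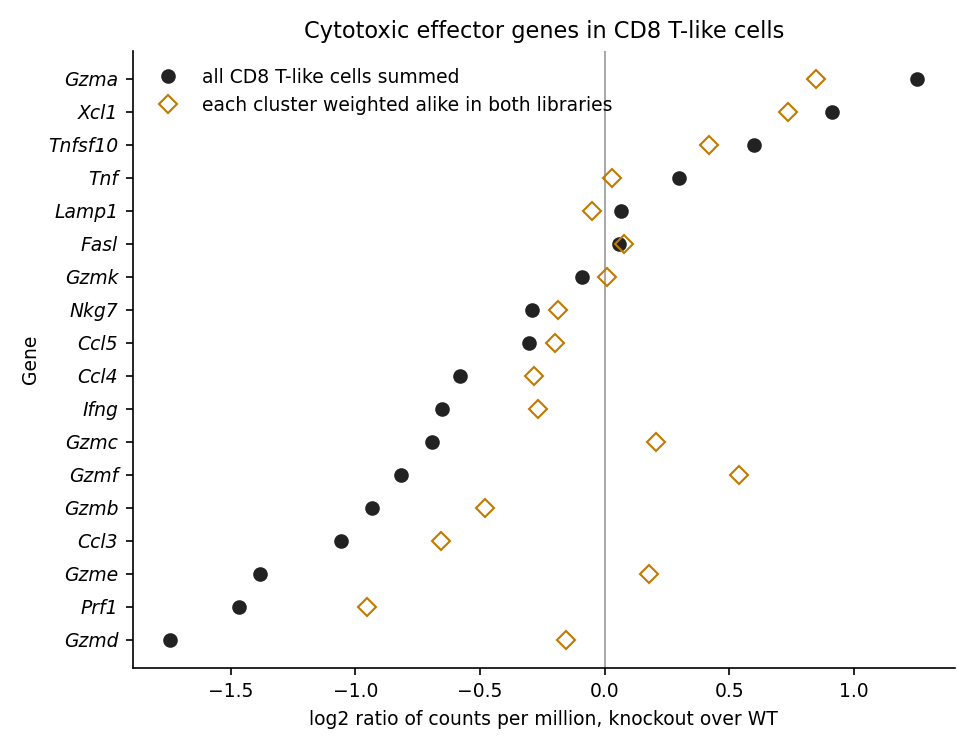
Log2 ratio of CPM, knockout over WT, of each measured cytotoxic effector gene in CD8 T-like cells; filled circles are all cells summed and open diamonds weight each cluster alike in both libraries (1 library per group, no error bars drawn). Prf1 stays low under both, at -1.47 and -0.95, while Gzmf stands at -0.82 and 0.54.

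The rule for named genes placed, among others, Ccl1 (118 and 33.1 CPM), also a leading gene of T cell cluster 12 and of the CD4 T-like cluster, Cd4 (9.64 and 2.00 CPM) and Tshz3 (5.92 and 0.387 CPM) among the genes most clearly higher in CD8 T-like cells of the knockout library, and Dlc1 (0.305 and 3.36 CPM) and Areg (0.186 and 5.30 CPM, in 7 and 33 cells) among those lower. Ccl1 was found in 282 and 109 cells of the class, with 45.6% and 73.5% of its UMIs in 10 cells. Cd4 is a marker of another class, and 107 knockout and 38 WT CD8 T-like cells held a UMI of it. Cyct had 0 UMIs in the knockout library and 198 in the WT library, at least 79.5-fold lower against a floor of 3 UMIs per library, a bound that takes the count of the other library as exact. Syce1 had 61 and 0 UMIs, at least 16.9-fold higher on the same floor. Several rested on few cells: Gcg, at least 36.9-fold lower on that floor with 0 and 92 UMIs, came from 4 WT cells, and Prss2 from 18 knockout cells.

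In macrophage-like cells, part of the inflammatory and antigen presentation lists was higher in the knockout library. Il1b (chromosome 2, 129364570 to 129371139), which encodes interleukin 1 beta, was at 96.1 and 45.0 CPM, a ratio of 2.13 (2.02 to 2.26). Cd86, a costimulatory ligand gene, was at 274 and 170 CPM, Ptgs2, which makes prostaglandin, at 98.8 and 48.9 CPM, and the T cell attractant Cxcl9 (chromosome 5, 92321347 to 92328079) at 1167 and 843 CPM. Of 17 measured inflammatory macrophage genes, 9 were at least 1.5-fold higher and 0 as much lower, and their median was 0.59. Under equal weights per cluster, 5 of the 9 remained at least 1.5-fold higher, and the log2 ratio of Il1b was 0.50 against 1.09. Of the 5 that remained, Il12b, also a leading gene of the mature dendritic-like cluster, had 98.9% and 93.5% of its UMIs in 10 cells. Il6, also among them, was higher in 2 of 5 clusters and lower in 3. The MHC class II gene H2-Eb1 was at 1730 and 1114 CPM and Ciita, the regulator of that pathway, at 82.8 and 45.9 CPM. The MHC class II presentation list had a median of 0.53, with 4 of 12 at least 1.5-fold higher, and was above 0 in 5 of 5 clusters, while the inflammatory list was above 0 in 4 of 5.

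Genes linked to suppressive macrophages went both ways, with 8 of 18 at least 1.5-fold higher, 3 as much lower and a median of 0.19. Arg1 (chromosome 10, 24915221 to 24927484), which encodes arginase, was at 1130 and 587 CPM and is among the leading genes of phagocyte cluster 2, whereas Il10, which encodes an anti-inflammatory cytokine, was at 8.11 and 24.8 CPM. Of lipid genes in these cells, Spp1 was at 629 and 342 CPM, Apoe at 3304 and 2107 CPM and lipoprotein lipase gene Lpl at 327 and 530 CPM. The lipid-associated macrophage list had a median of 0.069 and phagocytosis and efferocytosis genes 0.13. The ferroptosis and iron list stood at 0.16, and its member Slc7a11, which encodes a cystine importer, was at 25.4 and 8.69 CPM. Cell cycle genes had a median of -0.60, with 11 of 21 at least 1.5-fold lower. With each cluster weighted alike this median was -0.16, and 0 of the 11 remained at that size. The melanoma list was at -0.89 in these cells and the erythroid list at 4.01.

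Among genes taken by the rule, Lipg, which encodes endothelial lipase, was at 9.09 and 64.5 CPM in macrophage-like cells and is among the leading genes of phagocyte cluster 7, Fcrl5 at 8.73 and 46.4 CPM and the transcription factor gene Sox5 at 47.2 and 180 CPM. Higher in the knockout library were Htr7 (27.8 and 6.59 CPM), Pmepa1 (31.9 and 8.31 CPM) and Il12b (8.37 and 0.985 CPM), the last in 12 knockout and 14 WT cells. Cd209f came from 7 and 5 cells. First in place among the higher genes was Cd209a, a marker of cDC2-like cells, at 4.94 and 0.508 CPM in 20 and 9 cells, and H2-DMb2, one of the 4 higher MHC class II members, is a marker of those cells too.

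In monocyte-like cells, part of the inflammatory macrophage list was higher in the knockout library, with 5 of 16 members at least 1.5-fold higher. The list median was 0.42, above 0 in 2 of 3 clusters and -0.63 in phagocyte cluster 12. Cxcl2, a neutrophil attractant, was at 158 and 90.2 CPM and Tnf at 137 and 93.7 CPM, but Il1b was at 612 and 722 CPM. The median depended on the processing, at 0.21 with a clustering resolution of 2 and at 0.21 with at most 5% mitochondrial UMIs. The lipid-associated macrophage list had a median of -0.42 that was below 0 in 3 of 3 clusters, with 4 of 17 at least 1.5-fold lower and 2 as much higher. Across classes, the median of this list was below 0 in 11 of 12. Free RNA went the same way: the macrophage genes used to estimate it made up 0.422% of it in the knockout library and 0.810% in the WT library. The signs across classes therefore need not reflect expression by each class. With free RNA subtracted, the median in monocyte-like cells was -0.28. The lipid droplet coat gene Plin2 was at 271 and 411 CPM, whereas Fabp4 was at 4.71 and 2.02 CPM and Cd9 at 119.7 and 78.7 CPM. Gpnmb, at 17.7 and 30.1 CPM, was at 1687 and 1312 CPM in melanoma-like cells, and the melanoma list stood at -1.58 in monocyte-like cells. Oxidative phosphorylation stood at -0.29, and the erythroid list at -4.30. The rule named Inhba (58.9 and 11.1 CPM, in 154 and 23 cells, with 56.7% and 85.5% of the UMIs in 10 cells), Slc7a2 (78.3 and 19.7 CPM) and Fgf13 (114 and 32.2 CPM) among the higher genes and Pparg (22.9 and 49.6 CPM) and Ms4a7 (27.5 and 59.0 CPM) among the lower. Inhba and Slc7a2 are also among the leading genes of phagocyte cluster 0, and Ms4a7 is a marker of macrophage-like cells. These values may therefore depend on the cluster borders. S100a8, at 6.73 and 17.9 CPM, of which free RNA gave an estimated 67.3% and 13.4%, was higher rather than lower in the knockout library under 4 alternatives, and Retnla came from 20 and 5 cells.

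In cDC1-like cells, part of the interferon gamma response list was higher in the knockout library, with 11 of 20 at least 1.5-fold higher, 0 as much lower and a median of 0.62. Its members Tap1, Psmb8 and Psmb9 were slightly lower, at log2 ratios of -0.20, -0.12 and -0.18, each in 2 of 2 clusters. Cxcl9 was at 982 and 243 CPM, a ratio of 4.04 (3.74 to 4.36), with 53.2% and 73.6% of its UMIs in 10 cells of each library, and Gbp5, an interferon-induced GTPase, at 166 and 48.9 CPM. Cd40, the receptor for T cell help, was at 118 and 33.1 CPM and Tnf at 117 and 30.0 CPM, the last with 82.5% and 76.4% of its UMIs in 10 cells. Costimulation genes had a median of 0.54, T cell attracting chemokines 0.73 and MHC class II presentation -0.30. In neutrophil-like cells the interferon gamma response list had a median of 0.45, with 7 of 19 at least 1.5-fold higher, and Gbp2 was at 1092 and 628 CPM. The type I interferon list stood at 0.36 and MHC class I presentation at 0.38 there. Both interferon gamma medians were above 0 in 2 of 2 clusters.

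The type I interferon response list had a median below 0 in 8 of 12 classes, NK-like and Treg-like cells among them. In NK-like cells its median was -0.46, with 6 of 19 at least 1.5-fold lower, among them Ifit3 at 8.87 and 26.4 CPM (60 UMIs in the WT library); with members of at least 200 UMIs the median was -0.12. In Treg-like cells it was -0.57, with 9 of 18 at least 1.5-fold lower and 1 as much higher, but 0.10 when restricted to barcodes above the UMI threshold. It was below 0 in 1 of 2 Treg-like clusters, and 4 of the 9 remained at least 1.5-fold lower under equal weights per cluster. NK activation genes had a median of -0.053 in NK-like cells and cytotoxic effectors -0.12, where Gzma was at 5789 and 4882 CPM and Gzmb at 1171 and 1594 CPM. In Treg-like cells the Treg effector list was at -0.15 and the cell cycle list at 0.41; Top2a, a gene of dividing cells, was at 610 and 365 CPM and the Treg chemokine receptor gene Ccr8 at 19.8 and 47.6 CPM.

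Smaller classes were read by the same lists. Mature dendritic-like cells of the knockout library had more Ccl17 (663 and 148 CPM, in 128 and 34 cells, with 58.3% and 85.4% of the UMIs in 10 cells) and Ccl22 (1398 and 801 CPM), chemokines that attract CCR4+ T cells. In phagocyte cluster 0 the inflammatory macrophage list was at 0.54 and Cxcl10 at 1060 and 711 CPM. In non-classical monocyte-like cells that list was at -0.79, and hypoxia and glycolysis genes at -0.60. Cxcl2 was at 17.02 and 104 CPM there, in 57 and 21 cells, and the 10 WT cells with most of it held 94.8% of the WT UMIs; free RNA gave an estimated 43.6% and 4.8%. In cDC2-like cells myeloid attracting chemokines stood at -0.76 and the unfolded protein and integrated stress response list at 0.16. In lymphoid cluster 6, Ifng was at 72.6 and 19.03 CPM, in 29 and 18 cells, and 10 knockout cells held 82.6% of the knockout UMIs. The melanoma list was lower in the knockout library in 11 of 11 classes where it was measured. Free RNA went the same way: the melanoma genes used to estimate it made up 0.0588% of it in the knockout library and 0.199% in the WT library. The list values therefore need not reflect expression by the immune cells.

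**Figure D3:**
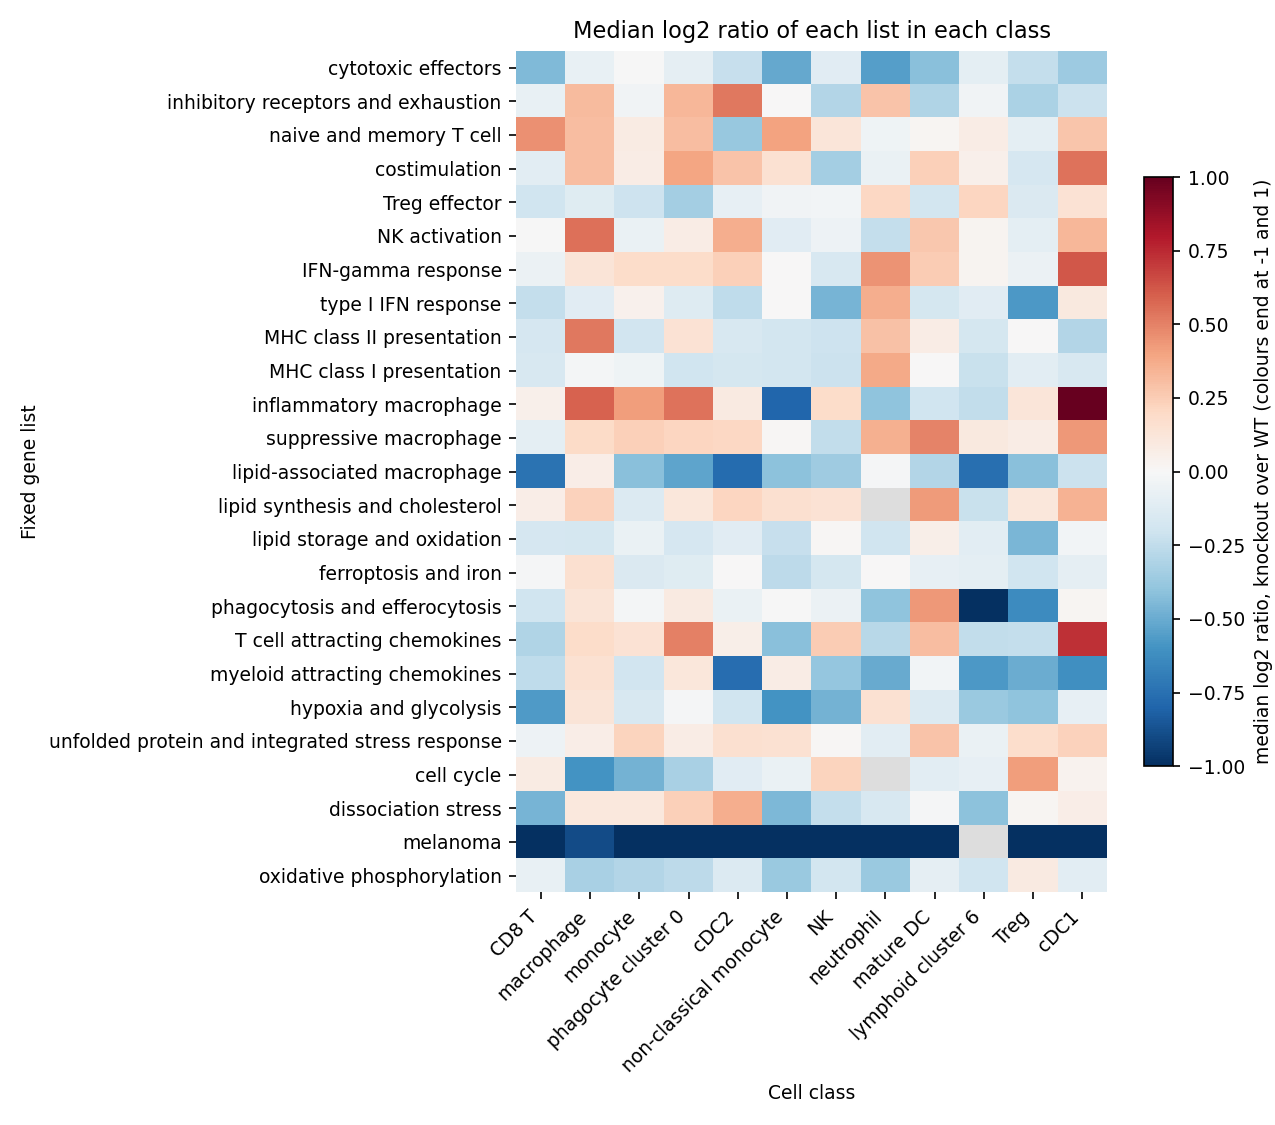
Median log2 ratio, knockout over WT, of each fixed gene list in each of 12 cell classes; colours end at -1 and 1, grey marks lists with too few measured members, and the erythroid list is left out. The melanoma list is below 0 in each class where it was measured, and the inflammatory macrophage list is at 0.59 in macrophage-like cells and at -0.79 in non-classical monocyte-like cells. Melanoma genes were also a smaller part of free RNA in the knockout library.

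**Figure D4:**
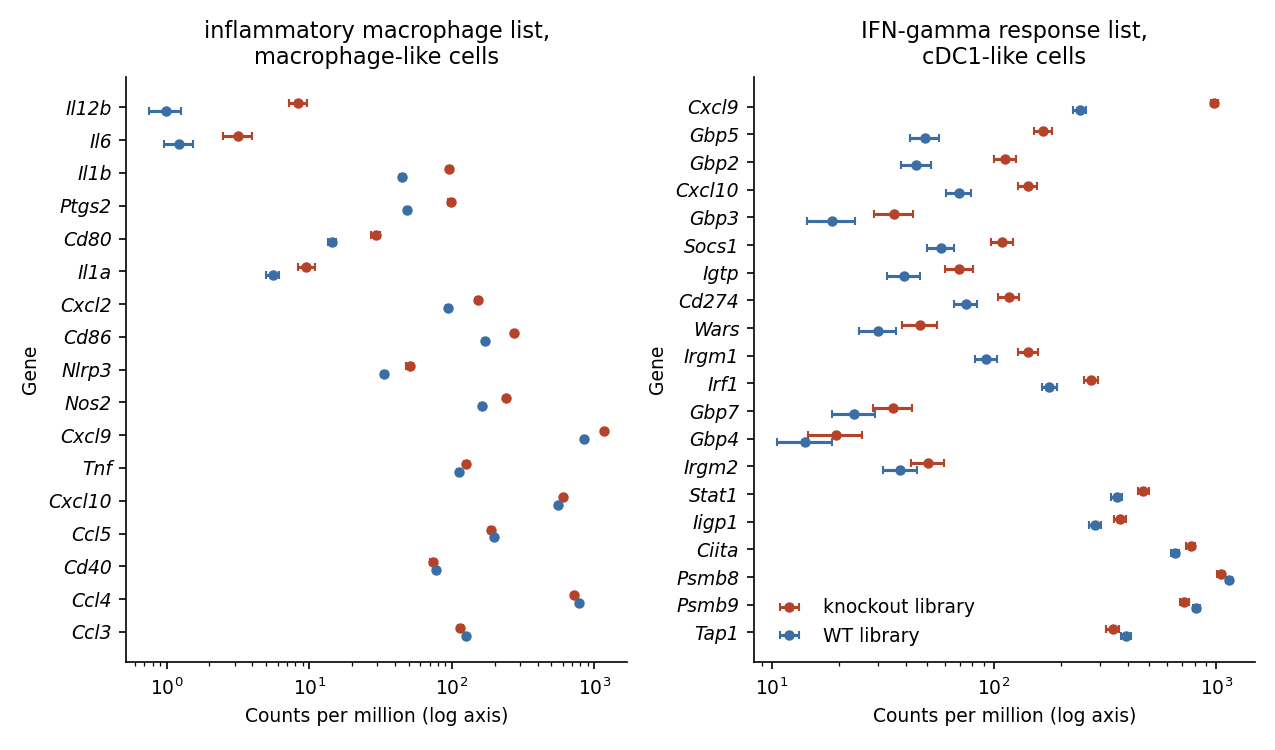
CPM on a log axis of each measured member of the inflammatory macrophage list in macrophage-like cells and of the interferon gamma response list in cDC1-like cells, in the knockout and WT libraries; bars are exact Poisson 95% intervals, which cover counting error only. In cDC1-like cells Cxcl9 is at 982 and 243.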

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

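Tests chosen only after the result was seen were the free RNA tests of cytotoxic effectors and of haemoglobin and the reading of the monocyte share under marker gates. The weighting of clusters alike and the repeat of cell calling on thinned barcodes were added after seeing the data, with their criteria set before their values were seen. Cells outside the sorted population were present above the limit that a count of 0 allows. Melanoma-like cells were 0.480% of kept cells in the knockout library (53 cells) and 2.44% in the WT library (223 cells). Fibroblast-like cells were 0.281% (31 cells) and 0.863% (79 cells). A CD45 sort should remove both.

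The smaller macrophage-like share and larger monocyte-like share of the knockout library were set against technical explanations. With WT barcodes thinned to matched depth before cells were called again and gated, the macrophage log2 share ratio was -1.38, with marker gates alone -1.29, and among cells of at least 10000 UMIs the log2 ratio of macrophage-like per monocyte-like cells was -2.38. These values argue against depth and cluster borders as the whole cause of the macrophage difference, and against small cells missing from the WT library as the whole cause of the shift between both types. The monocyte log2 share ratio was 0.65 with gates and 1.21 with clusters, so cluster borders may account for part of the monocyte difference and stay open for it. No biological explanation was tested: a difference in the immune response to DGAT1-deficient tumours, variation between tumours and differences in digestion or tumour size stay open, because 1 library per group cannot separate them.

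Lower cytotoxic effectors in CD8 T-like cells of the knockout library kept a list median of -0.45 after free RNA was subtracted and of -0.52 without the 1% of cells with most of these UMIs, which argues against both as the whole cause. A different mix of CD8 T clusters stays open for the list: at equal mix its median was -0.021, which met the criterion set beforehand for the mix as the cause. Because members then went both ways, from Prf1 at -0.95 to Gzma at 0.85, and because granzyme genes and Prf1 were themselves among the genes leading those clusters, this was read as undecided, a reading adopted after the value was seen. The lower list median may therefore come in part or in full from a difference in which CD8 T-like states were present. No biological cause was tested.

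Haemoglobin genes differed widely in phagocytes, at 85.3 and 5.67 CPM in macrophage-like cells, 24.6 and 499 CPM in monocyte-like cells and 269 and 8.23 CPM in phagocyte cluster 0. In the higher library the 10 cells with most haemoglobin UMIs held at least 96.4% of them in each of these classes, consistent with red blood cell RNA in a few cells. Free RNA gave as little as 0.832% of them in the higher library, which argues against it as the whole cause.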

How the results depend on the processing

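The alternatives that weighted each cluster alike, left unnamed cells out of the denominator or called cells again on thinned WT barcodes before gating, and the minimums of the marker gates were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no result comes from a test. The share ratios of named classes and numbered clusters kept their direction under the alternatives that gave a value, except phagocyte cluster 0, whose interval spans 0 and which stood at -0.0061 without unnamed cells. New clusters took the class most of their cells had before, so only the alternatives with marker gates assigned classes anew. Unnamed cells went from -1.77 to 0.18 with marker gates, 0.16 with thinned barcodes and gates and 1.12 above the UMI threshold, and unnamed phagocytes from 0.39 to -0.38 with doublets kept. Of the share values, 125 share values moved by less than their counting interval and 24 by more, unnamed cells left out. Of list values 799 were within it, 201 moved and 5 changed sign; of gene values 785, 107 and 10. The cause was not tested for any of them, except that the UMI threshold keeps fewer cells (6328 and 3943). Counts limit rare classes most. Ratios below are log2.

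With only barcodes above the UMI threshold, shares were CD8 T 0.046, CD4 T 5.62, NK 1.51, macrophage -1.63, monocyte 1.74, non-classical monocyte 3.37, mature dendritic 1.02 and plasmacytoid dendritic 2.80. Marker gates gave CD8 T 0.046, CD4 T 1.40, macrophage -1.29, monocyte 0.65 and cDC2 0.10. Thinned barcodes called again and gated gave CD8 T 0.047, CD4 T 1.53, neutrophil 0.60, monocyte 0.66 and cDC2 0.35. Macrophage shares were -1.53 with at least 1000 UMIs and -1.61 with at most 5% mitochondrial UMIs, where the monocyte share was 1.07.

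Signs changed above the UMI threshold for the type I interferon list in Treg (0.10), the interferon gamma list in CD8 T (0.0045), cytotoxic effectors in NK (0.061), Cstdc4 in monocyte (-0.088), S100a8 in monocyte (2.28) and Gzma in Treg (-0.85). At 1000 UMIs they changed for S100a8 (0.30), Ngp in neutrophil (-2.74) and Gzma in Treg (-2.09), and at 5% mitochondrial UMIs for S100a8 (0.34), Ngp (-2.71) and Gzma (-0.92). S100a8 was 1.06 at resolution 2, myeloid attracting chemokines in CD8 T 0.46 with free RNA subtracted, and Treg effector genes in Treg 0.051 with clusters weighted alike.

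With clusters weighted alike, CD8 T medians were -0.021 for cytotoxic effectors, -0.42 for hypoxia and 0.11 for naive and memory genes, Treg type I interferon -0.36, macrophage cell cycle -0.16 and macrophage inflammatory genes 0.50. Median-of-ratios scaling gave CD8 T cytotoxic effectors -0.51 and hypoxia -0.64, and monocyte lipid-associated genes -0.47. Free RNA subtraction gave naive and memory genes 0.32 and monocyte lipid-associated genes -0.28. Members of at least 200 UMIs gave type I interferon medians of -0.12 in NK and -0.37 in Treg. Above the UMI threshold, CD8 T cytotoxic effectors were -0.43 and monocyte lipid-associated genes -0.58. At 1000 UMIs, macrophage inflammatory genes were 0.53 and monocyte lipid-associated genes -0.29. At 5% mitochondrial UMIs, macrophage MHC class II was 0.54, cell cycle -0.73 and inflammatory genes 0.53, and in monocyte inflammatory genes were 0.21 and lipid-associated genes -0.46. With doublets kept, macrophage MHC class II was 0.57, cell cycle -0.40 and inflammatory genes 0.50, and in monocyte inflammatory genes were 0.33 and lipid-associated genes -0.27. At resolution 2, macrophage cell cycle was -0.67 and inflammatory genes 0.51, and monocyte inflammatory genes 0.21. Thinned cells gave monocyte inflammatory genes 0.27.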

Other observations

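No test was added for these values, which were chosen after they were seen. Melanoma-like cells that passed the sort, 53 in the knockout library and 223 in the WT library, fell below the 100 cells set for a comparison. In them the unfolded protein and integrated stress response list had a median log2 ratio of 0.36, with 5 of 16 members at least 1.5-fold higher in the knockout library. Its members Trib3, at 41.0 and 23.2 CPM, and Atf4, at 219 and 139 CPM, belong to the integrated stress response, and Herpud1, at 77.7 and 46.1 CPM, to the response to unfolded protein. The ferroptosis and iron list stood at 0.12: Slc7a11, which encodes a cystine importer that protects against ferroptosis, was at 19.1 and 6.39 CPM, and Gpx4, the peroxidase that does so, at 495 and 497 CPM. The lipid synthesis and cholesterol list was at 0.089 and the lipid storage and oxidation list at -0.084. Cytotoxic effectors were at -2.02 in these barcodes, with Prf1 at 1.27 and 18.7 CPM. The WT melanoma-like barcodes thus held more RNA of cytotoxic genes. Most other immune lists were below 0 as well, with suppressive macrophage genes at -0.95 and MHC class II presentation at -0.016. The interferon gamma response stood at 0.20. Whether RNA of immune cells also shifted the other values in these barcodes was not tested.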
